A study of Lactuca sativa with 12 samples.

How the data were processed

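Poly(A) RNA of lettuce (*Lactuca sativa*) leaf, root and stem was measured with HIT-ISOseq, a PacBio long-read protocol for full-length cDNA, in 2 libraries per tissue named s1 and s2 in the labels. Per the labels, each library carried its own barcoded adapter and was read in high-fidelity mode. The labels also list short-read libraries of the same tissues, which were not analysed here. Every one of the 6 long-read libraries was grouped by the tissue in its title, and 0 columns of per-sample values were left unmapped.

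The gene table that the authors deposited holds whole-number counts per gene and library, together with CPM, which are those counts scaled to an equal total per library. The isoform table that the authors deposited holds whole-number counts of unique molecular identifiers (UMIs) per isoform and library, with the corresponding CPM. Each isoform name in that deposited table carries a structural category: full splice match (FSM), incomplete splice match (ISM), a combination of annotated splice sites absent from the reference (NIC), or at least 1 splice site absent from the reference (NNC). The other deposited tables hold no measurement and assign genes to Gene Ontology (GO) terms and to KEGG orthology groups (KOs). Gene models on the build Lsat_Salinas_v7 were made with StringTie 2.2.1 in merge mode, per the file headers, and the coordinates given are those of these models. Their sequence names were turned into chromosome numbers through a RefSeq annotation of a later lettuce build, on which 98.6 to 99.2% of the genes of a sequence lay on the same chromosome, and no coordinate was taken from that build. The aligner, the counting tool and the treatment of reads shared between similar genes or between strands are not given in the sources used here. Values of overlapping genes and of near-identical copies, such as those of the Rubisco small chain, are therefore uncertain.

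Gene counts summed to between 1909230 and 2475316 per library and isoform UMIs to between 1253709 and 1630810. A count of 3, taken as the detection floor, corresponds to 1.21 to 1.57 CPM for genes and 1.84 to 2.39 CPM for isoforms. Counting intervals are 95% intervals (Wilson for shares, exact binomial for ratios) and, like the floor, cover counting error only. The counts of the libraries of a tissue were compared by a chi-square test over genes: chi-square per degree of freedom was 21.2 in leaf, 10.6 in root and 39.6 in stem, far above sampling noise, so no library was treated as a duplicate. No label says whether s1 and s2 came from separate plants, so p-values measure the spread between these samples, which may be technical.

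Genes and isoforms were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by tissue (minimum count 10, minimum total 15), TMM factors, robust quasi-likelihood fits of tissue over all 6 libraries (3 residual degrees of freedom) and quasi-likelihood F tests of leaf vs root, leaf vs stem and root vs stem. The filter left 19601 of 31297 genes and 24280 of 69973 isoforms. A call required a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. A gene or isoform was called enriched in a tissue when it was higher there than in each of the other 2 tissues; these calls rest on a pair of tests that share the libraries of that tissue. Standard errors (SE) of log2 fold changes are the fold change over the square root of the F statistic. Values are given as mean CPM ± SD over the 2 libraries of a tissue. A fold against a tissue at 0 counts is a lower bound against 3 counts over its libraries together, and one against 1 to 3 counts is the ratio of CPM with its counting interval. The median log2 fold change over all tested genes lay between -0.07 and -0.02 with TMM factors.

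Isoform usage was tested with diffSpliceDGE of edgeR, with isoforms in the place of exons, over genes with 2 or more tested isoforms; a call required a Simes adjusted p under 0.05 and a change of at least 10 percentage points in the share of 1 isoform among the UMIs of the tested isoforms of its gene. Gene lists were tested with camera of limma 3.58.1 (preset correlation between genes 0.01, lists of at least 5 tested members, Benjamini-Hochberg over lists). List calls were also computed with a correlation estimated from the data, and of the calls in the 3 comparisons none held under it. That estimate rests on 3 residual degrees of freedom. In leaf vs root it lay below the preset for carotenoid (-0.0126) and glyoxylate genes (-0.0116), and their calls were lost too. A call lost under it therefore does not show that correlation between members produced the call. The lists were photosynthesis, antenna proteins, carbon fixation, chlorophyll and porphyrin metabolism, carotenoid biosynthesis, glyoxylate and dicarboxylate metabolism (photorespiration), phenylpropanoid, flavonoid, terpenoid backbone, sesquiterpenoid and triterpenoid, zeatin and brassinosteroid biosynthesis, cutin, suberin and wax, nitrogen, starch and sucrose and glutathione metabolism, plant hormone signal transduction, plant-pathogen interaction, the plant circadian rhythm, DNA replication, ribosome and spliceosome (KEGG), and peroxidase activity, cellulose biosynthesis, cell wall, xyloglucan metabolism, lignin catabolism (laccases), nucleosome, microtubule-based movement, oligopeptide and nitrate transport, channel activity (aquaporins), terpene synthase activity, nutrient reservoir (germin-like), lipid transport, defense response, NBS-LRR (ADP binding), transcription factor activity and response to auxin (GO). Photosynthesis and antenna proteins also served as markers of green tissue, nucleosome and DNA replication of dividing tissue, and cellulose biosynthesis and laccases of xylem. In 37 of the lists enough members were tested; brassinosteroid biosynthesis had 1 tested member and was not testable.

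Comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, with these departures. The deposited KEGG table gives KOs without pathways, so list members were taken by KO, a choice made after the table was seen and before any test. For the same reason, over-representation among tissue-enriched genes was tested on GO terms in place of pathways (one-sided Fisher's exact test, terms with at least 10 members, 920 terms, background of 16412 tested genes with a term). Identifiers of the isoform table matched 0 transcript identifiers of the gene models, so the kinds of splicing difference were not analysed here. Named genes were the 10 enriched genes of highest mean CPM per tissue and the 10 of largest smaller fold change, with a KO or GO term and at least 50 CPM in that tissue, up to 3 called members per passing list with the highest mean over all libraries, and up to 8 called usage genes per comparison with at least 50 UMIs in every library. Genes named outside this rule are marked as chosen after their values were seen.

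The s number was checked for pairing before calls of blocked and unblocked fits were compared. The s1 minus s2 differences in log2(CPM + 1) correlated across 18080 genes at 0.308 between leaf and root, 0.464 between leaf and stem and 0.246 between root and stem, and over isoforms at 0.300, 0.455 and 0.226. Every correlation exceeded 0.1, so the number was taken to pair the libraries, and a fit with the number as a block (2 residual degrees of freedom) is given beside results where it changed a call or moved a count by over 1.5 times. The pairing comes from these values, since no label states a shared plant, day or batch. Libraries that differ along a common axis could be numbered so by luck, so the rule cannot establish a shared source. Results with the block depend on this pairing.

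Alternatives were DESeq2 1.42.0 with its own size factors, RLE factors, no low-count filter, an adjusted p under 0.01, the replicate block, fits of only the 2 tissues compared, and each library left out in turn, where the remaining library of that tissue is assumed to vary like the others. For usage they were limma voom with diffSplice, a minimum isoform share of 0.05 and no minimum change of share; for GO terms, all tested genes as background. Added after the data were seen were a usage test with the gene UMI total as offset and as the base of the share (genes with at least 10 UMIs per library), the same with the block, and GO terms of genes called with the block. A pseudocount alternative did not apply to counts. Correlations and principal components used log2(CPM + 1) of genes with a total of at least 60 counts, and Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

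Each test but Fisher's was first tested on simulated data drawn from the measured means, depths and spread, with changes planted in leaf. With 200 of 18655 genes changed, leaf vs root recovered 4.62% of 4-fold, 57.6% of 16-fold and 80.3% of 64-fold changes, with 6 false calls, and leaf vs stem 1.54%, 54.5% and 82.0%, with 6 false calls. With 4000 of 18272 genes changed, leaf vs root recovered 54.8%, 92.2% and 97.0% of these sizes (154 false calls). For isoforms with 200 changed among 21803, leaf vs root recovered 6.67%, 58.1% and 70.5%. The usage test recovered 17.6% of 199 switched genes among 5579 in leaf vs root (2 false calls), and the test with the gene total as offset 23.7% of 198 among 5435 (3 false calls). Camera called the 1 changed list and 0 of 20 unchanged lists, and Fisher's test the 1 planted term and 0 of 200 others. The simulated genes were drawn independently. The camera result therefore does not cover lists with correlated members, such as the antenna proteins (estimated correlation 0.917).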

Results

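Full-length poly(A) transcripts of garden lettuce were counted in leaf, root and stem, with 2 HIT-ISOseq libraries per tissue, to ask which genes and isoforms differ between the tissues. Gene counts summed to 2191439 in leaf s1, 2166812 in leaf s2, 1909230 in root s1, 2169747 in root s2, 2187368 in stem s1 and 2475316 in stem s2. Between 23550 (leaf s1) and 27629 (stem s1) genes had any count in a library, and 18995 genes had a count in all 6. A single count, below the detection floor of 3, was enough here. Isoform UMI totals ran from 1253709 in root s1 to 1630810 in stem s2. The 10 most abundant genes took 4.57% of the counts in stem s2 and between 6.74 and 8.98% in the other libraries.

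Across 18080 genes, log2(CPM + 1) correlated at r = 0.918 between the root libraries, 0.872 between the leaf libraries and 0.764 between the stem libraries. These are correlations across genes, which are not independent replicates. Libraries of different tissues correlated at 0.358 to 0.710. The closest pairs across tissues were leaf s2 with stem s2 (0.710) and root s1 with stem s1 (0.708). The stem libraries differed over 4-fold in 1687 genes, against 866 in leaf and 404 in root. The first principal component held 59.3% of the variance and placed root and leaf at opposite ends with stem between them, and the second, with 20.99%, set stem apart.

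**Figure D1:**
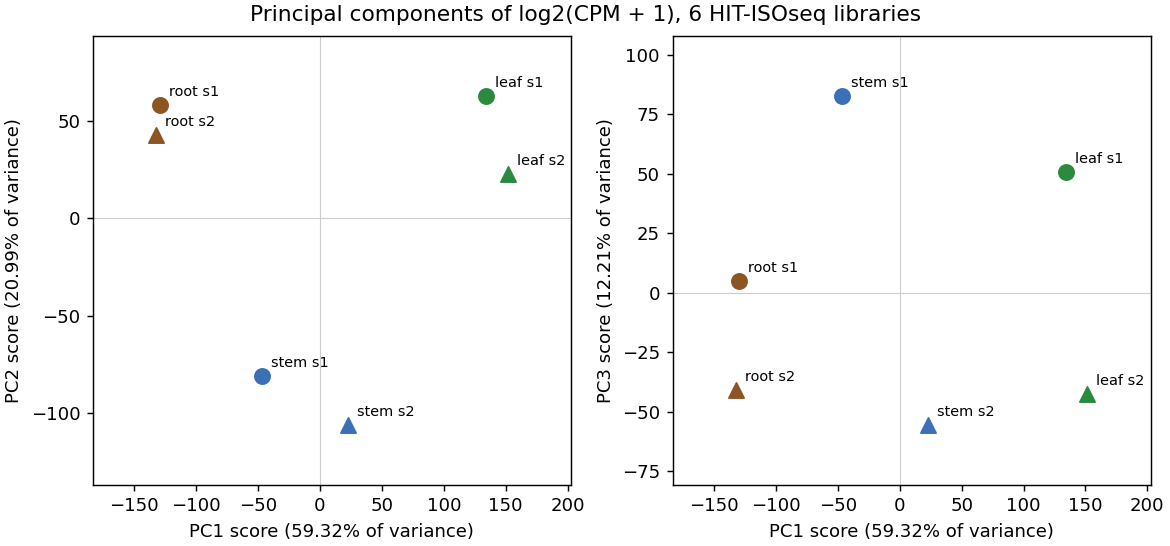
Principal components of log2(CPM + 1) over 18080 genes, component 1 against component 2 and against component 3, with 1 point per library (circles s1, triangles s2) and the percent of variance on each axis. Leaf and root lie at opposite ends of component 1 (59.3%), stem is apart on component 2 (20.99%), and on component 3 (12.2%) the s2 library of each tissue lies below its s1 library.

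Leaf exceeded root in the genes of the photosynthetic apparatus. The photosystem II 10 kDa protein gene LOC111884730 (Lsat_Salinas_v7 chromosome 7, 190060347 to 190061714, minus strand) stood at 9747 ± 1414 CPM in leaf and 13.6 ± 7.47 CPM in root (SD, n = 2), a log2 fold change of 9.81 (SE 1.03). LOC111914553 (chromosome 7, 167089864 to 167091354), a light-harvesting chlorophyll a/b binding protein of photosystem I, stood at 8705 ± 888 CPM in leaf and 7.08 ± 4.80 CPM in root (log2 fold change 10.58, SE 1.41). Of 61 tested photosynthesis genes 51 were higher in leaf and 10 did not pass the test. Adjusted over the list alone, 53 were higher and 1 was lower. The median log2 fold change was 8.03, or 7.09 with genes at 0 counts placed at their bound. The antenna proteins, which bind the chlorophyll that collects light, were higher in leaf in 26 of 27 genes (27 adjusted over the list alone), with a median of 10.11, or 9.46 with genes at 0 at their bound. Chlorophyll and porphyrin genes were higher in leaf in 30 of 47 (37 higher and 2 lower adjusted over the list alone, 33 and 1 with the replicate block, median 3.22), among them the cyclase LOC111879482 at 1220 ± 135 CPM in leaf and 17.6 ± 10.6 CPM in root. That list also holds LOC111904638, whose other KO is a phenylcoumaran benzylic ether reductase, at 167 ± 44.8 CPM in leaf and 3.15 ± 0.755 CPM in root. Camera gave Benjamini-Hochberg adjusted p = 4.25e-22 for photosynthesis, 6.625e-17 for antenna proteins and 1.112e-11 for chlorophyll. They had adjusted p = 0.361, 0.487 and 0.361 with an estimated correlation.

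Carbon fixation genes were higher in leaf in 24 of 45 and lower in 5 (26 and 8 adjusted over the list alone, median 2.64). They include the Rubisco small chain gene LOC111917913 (chromosome 4, 304914076 to 304943438) at 13663 ± 5838 CPM in leaf and 10.3 ± 0.934 CPM in root. Overlapping and near-identical copies leave the value of each copy uncertain. Photorespiration-related glyoxylate genes were higher in leaf in 12 of 36 (14 higher and 1 lower adjusted over the list alone, median 0.76). The ratio of leaf to root was 1940 (counting interval 663.4 to 9408) for the glycine hydroxymethyltransferase gene LOC111895989. Carotenoid genes were higher in leaf in 25 of 50 and lower in 5 (28 and 7 adjusted over the list alone, median 1.648). Zeaxanthin epoxidase LOC111885712 stood at 121 ± 39.6 CPM in leaf and 1.45 ± 0.563 CPM in root. In contrast, LOC111913469, which carries KOs of salicylate hydroxylase and zeaxanthin epoxidase, was higher in root (187 ± 12.4 against 35.03 ± 19.5 CPM). Circadian rhythm genes were higher in leaf in 25 of 61 and lower in 3 (33 and 6 adjusted over the list alone, median 1.99). The blue-light receptor gene cryptochrome 1, LOC111921254, stood at 145 ± 15.7 CPM in leaf and 22.9 ± 3.11 CPM in root. The root-high circadian member LOC111881715 (78.4 ± 10.9 CPM in root, 2.53 ± 1.64 CPM in leaf) also carries KOs of a mitochondrial protein and a basic endochitinase. By camera, adjusted p was 1.122e-04 for carbon fixation, 3.098e-04 for glyoxylate, 1.326e-04 for carotenoid and 7.856e-06 for circadian rhythm genes. Each of these lists had adjusted p = 0.361 with an estimated correlation.

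Root exceeded leaf in genes of phenylpropanoid and peroxidase metabolism, which supply and polymerise lignin precursors. Cinnamate 4-hydroxylase LOC111876528 (chromosome 9, 18744518 to 18747244, plus strand) stood at 2647 ± 482 CPM in root and 142 ± 0.810 CPM in leaf (SD, n = 2), a leaf vs root log2 fold change of -3.88 (SE 0.46). Of 198 phenylpropanoid genes 72 were higher in root and 15 in leaf (88 and 21 adjusted over the list alone, median -1.68). One of them, LOC111881849, carries the KO of ubiquitin hydrolase 36/42 beside that of a peroxidase and stood at 2169 ± 63.1 CPM in root and 25.0 ± 8.56 CPM in leaf. Peroxidase genes were higher in root in 38 of 102 and in leaf in 5, or 10 with the replicate block (44 and 7 adjusted over the list alone, median -1.87). LOC111903792 had 1072 counts in root and 0 in leaf, at least 381.8-fold higher. Laccases, which oxidise lignin precursors, were higher in root in 6 of 14 (8 higher and 1 lower adjusted over the list alone, 6 and 1 with the block, median -2.86). LOC111919497 stood at 271 ± 1.496 CPM in root and 1 count in leaf. Adjusted p by camera was 2.485e-07 for phenylpropanoid, 1.246e-06 for peroxidase and 0.0367 for laccase genes. The same lists had adjusted p = 0.361, 0.361 and 0.649 with an estimated correlation. The laccase call was lost with the replicate block (adjusted p = 0.0616), without leaf s1 (0.197) and without root s2 (0.0522).

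Histone and replication genes were lower in leaf than in root. The nucleosome list was higher in root in 60 of 131 genes (81 adjusted over the list alone, median log2 fold change -2.08). Histone H2B LOC111911137 stood at 442 ± 22.2 CPM in root and 22.8 ± 12.8 CPM in leaf. DNA replication genes were higher in root in 6 of 51 (2 adjusted over the list alone, median -0.79). Proliferating cell nuclear antigen LOC111916510, the sliding clamp of DNA polymerase, stood at 68.2 ± 37.2 CPM in root and 2.52 ± 0.345 CPM in leaf. In the ribosome list 42 of 407 genes were higher in leaf and 21 in root (38 and 14 adjusted over the list alone), while DESeq2 called 40 higher in leaf and 63 in root. The median (-0.73), the mean (-0.33) and camera pointed to root. Its leaf-high members include S9 (LOC111914100, 490 ± 203 against 44.0 ± 1.54 CPM) and L6 (LOC111893364), KO names used for bacterial and organelle ribosomes. Its root-high members include S3Ae (LOC111907381, 703.1 ± 152 against 125 ± 34.4 CPM), a name used for cytosolic ribosomes. The higher root level of L37e (LOC111910265) passed at adjusted p = 0.0486 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and did not with the replicate block (0.0577). Camera adjusted p was 6.416e-14 for nucleosome, 0.00104 for DNA replication and 1.122e-04 for ribosome genes. These lists gave adjusted p = 0.565, 0.384 and 0.867 with an estimated correlation.

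Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3929 of 19601 between leaf and root, 2256 of them higher in leaf and the others in root. Adjusted p of the named genes by this test lay between 0.00604 for LOC111885712 and 0.0486 for LOC111910265. The count fell to 1535 without leaf s1, to 1033 without leaf s2 and to 0 without either root library. In the last fits 4782 (root s1 left out) and 4704 (root s2 left out) genes still had an unadjusted p under 0.05. Flavonoid genes (4 of 23 higher in leaf, 1 in root; 8 and 1 adjusted over the list alone; 11 and 1 with the replicate block) did not pass camera at adjusted p = 0.0553 and did with the block (0.0281; adjusted p = 0.523 with an estimated correlation). Nitrogen metabolism also missed the threshold, at adjusted p = 0.0525, with 9 of 41 genes higher in leaf and 5 in root (17 and 7 adjusted over the list alone; 15 and 7 with the block).

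**Figure D2:**
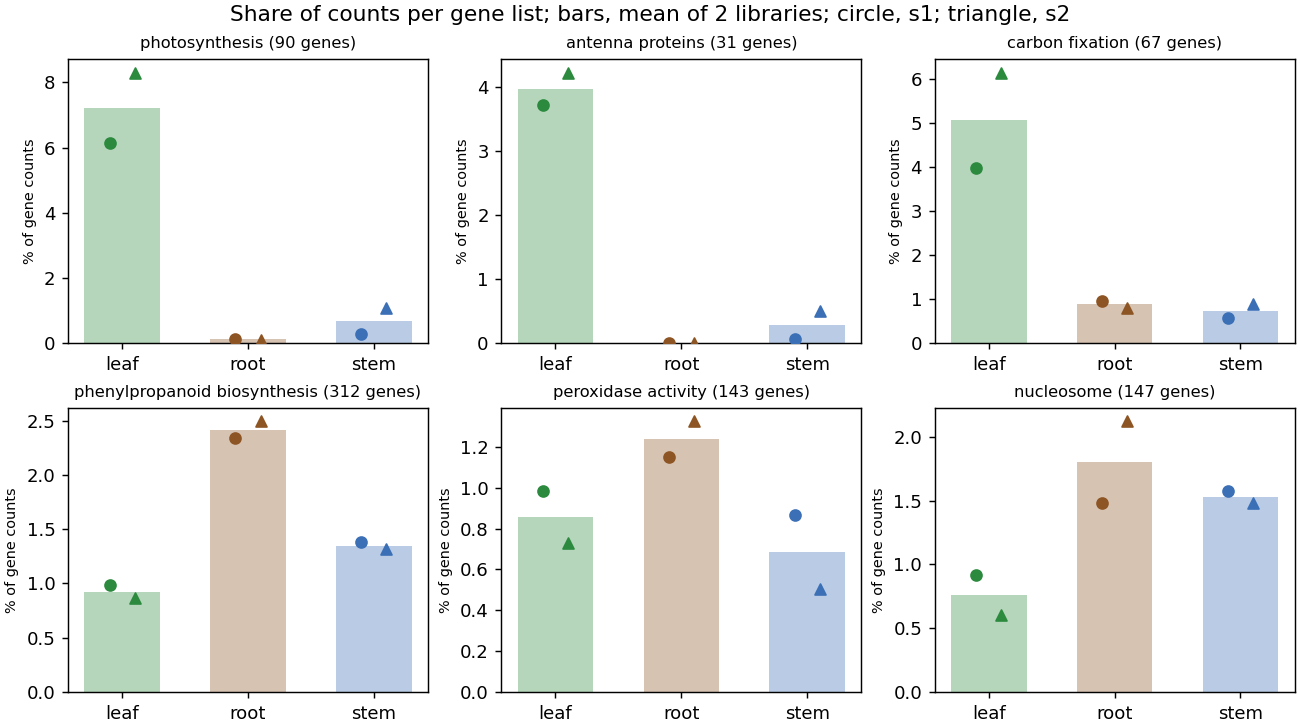
Share of all gene counts taken by each of 6 gene lists, in percent, by tissue; bars are the mean of 2 libraries, circles s1 and triangles s2. Photosynthesis genes took 6.16 and 8.30% of the counts in the leaf libraries, 0.133 and 0.111% in root, and 0.283 and 1.10% in stem s1 and s2.

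Leaf also exceeded stem in photosynthesis genes, by less than it exceeded root. Photosystem II 10 kDa protein LOC111884730 stood at 806 ± 506 CPM in stem (SD, n = 2), a leaf vs stem log2 fold change of 4.01 (SE 0.79). The antenna gene LOC111891773 (chromosome 5, 288936366 to 288937756) stood at 3998 ± 1289 CPM in leaf and 329 ± 283 CPM in stem (log2 fold change 4.02, SE 0.84). The stem libraries themselves differed here. Photosynthesis genes took 0.283% of counts in stem s1 (Wilson interval 0.276 to 0.290%) and 1.10% in stem s2 (1.08 to 1.11%). Antenna genes took 0.0703% (0.0668 to 0.0739%) and 0.503% (0.494 to 0.512%). Of 61 photosynthesis genes 22 were higher in leaf (53 higher and 1 lower adjusted over the list alone, 45 higher with the replicate block, median 3.56). Antenna genes were higher in leaf in 9 of 27 (24 adjusted over the list alone, 24 with the block, median 3.98). Chlorophyll genes were higher in 14 of 47, with 1 lower (30 and 2 adjusted over the list alone, 26 and 1 with the block, median 2.03). LOC111910617, annotated by GO with Rubisco activase activity, stood at 4925 ± 603 CPM in leaf, 14.5 ± 16.02 CPM in stem and 1.80 ± 1.896 CPM in root. By camera, adjusted p was 1.58e-19 for photosynthesis, 4.291e-14 for antenna and 1.567e-09 for chlorophyll genes. They had adjusted p = 0.448 with an estimated correlation for each of them.

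Carbon and nitrogen assimilation genes were higher in leaf than in stem. Carbon fixation genes were higher in leaf in 14 of 45 (24 higher and 4 lower adjusted over the list alone, 21 and 2 with the replicate block, median 1.74). Nitrogen metabolism genes were higher in 9 of 41 and lower in 1 (17 and 1 adjusted over the list alone, 16 and 1 with the block, median 1.93). Glutamine synthetase LOC111881770 stood at 2427 ± 290 CPM in leaf and 129 ± 42.7 CPM in stem. Ferredoxin-dependent glutamate synthase LOC111891706 stood at 579 ± 41.0 and 38.8 ± 0.663 CPM. Glyoxylate genes were higher in leaf in 10 of 36 and lower in 1 (10 and 1 adjusted over the list alone, median 0.60). Catalase LOC111878432, which removes hydrogen peroxide, stood at 936 ± 130 CPM in leaf and 36.7 ± 10.2 CPM in stem. Carotenoid genes were higher in 16 of 50 (24 higher and 4 lower adjusted over the list alone, 18 and 1 with the block, median 1.09). Circadian genes were higher in 12 of 61, with 1 lower (19 and 2 adjusted over the list alone, 17 and 2 with the block, median 0.66). The list took 0.259% (Wilson interval 0.253 to 0.266%) and 0.321% (0.314 to 0.329%) of counts in leaf s1 and s2, 0.131% (0.126 to 0.136%) in stem s1 and 0.647% (0.637 to 0.657%) in stem s2, so that stem s2 lay above both leaf libraries. Adjusted p by camera was 2.137e-06 for carbon fixation, 9.232e-06 for nitrogen, 6.817e-04 for glyoxylate, 4.56e-05 for carotenoid and 6.817e-04 for circadian genes. The same lists had adjusted p = 0.407, 0.448, 0.407, 0.407 and 0.448 with an estimated correlation. The circadian call was lost without stem s1 (adjusted p = 0.0580).

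Stem exceeded leaf in genes of chromatin, DNA replication, microtubule motors and cell wall loosening. Nucleosome genes were higher in stem in 31 of 131 (65 higher and 1 lower adjusted over the list alone, 57 with the replicate block, median -1.64). Histone H3 LOC111890174 stood at 392 ± 132 CPM in stem and 34.5 ± 18.4 CPM in leaf (log2 fold change -3.08, SE 0.56). DNA replication genes were higher in stem in 15 of 51 (18 adjusted over the list alone, median -0.93). The helicase subunit MCM2, LOC111912362, stood at 51.5 ± 10.1 CPM in stem and 3.22 ± 2.62 CPM in leaf. Microtubule-based movement genes were higher in stem in 10 of 66 and in leaf in 2 (19 and 3 adjusted over the list alone, 16 and 2 with the block, median -0.77). Kinesin 15, LOC111889633, stood at 42.2 ± 26.6 CPM in stem and 1.38 ± 1.31 CPM in leaf. Xyloglucan genes were higher in stem in 3 of 28 (4 adjusted over the list alone, 8 with the block, median -1.69). The xyloglucan transferase LOC111900228, with 499 counts in stem and 0 in leaf, was at least 155.5-fold higher in stem. Xyloglucan genes took 0.149% of counts in stem s1 (Wilson interval 0.144 to 0.154%) and 0.451% in stem s2 (0.443 to 0.460%). They took 0.0803% (0.0766 to 0.0841%) in leaf s1 and 0.200% (0.194 to 0.206%) in leaf s2, so that leaf s2 lay above stem s1. Camera adjusted p was 7.252e-14 for nucleosome, 9.811e-08 for DNA replication, 0.00106 for microtubule and 1.724e-04 for xyloglucan genes. These lists gave adjusted p = 0.448, 0.407, 0.548 and 0.448 with an estimated correlation. The xyloglucan call was lost without stem s2 (adjusted p = 0.0660).

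In leaf vs stem 6 further lists passed camera. Response to auxin (5 of 50 genes higher in leaf; 7 higher and 1 lower adjusted over the list alone; 8 and 1 with the block) passed at adjusted p = 0.0339 (0.424 with an estimated correlation). The auxin-induced SAUR gene LOC111899722 stood at 31.0 ± 9.66 CPM in leaf and 1.64 ± 1.68 CPM in stem. Oligopeptide and nitrate transport had 1 of 25 genes higher in leaf (1 adjusted over the list alone, 4 with the block; adjusted p = 0.00863, 0.448 with an estimated correlation). Flavonoid biosynthesis had 2 of 23 (2 adjusted over the list alone, 4 with the block; adjusted p = 0.0479, 0.448 with an estimated correlation). Cell wall genes were higher in stem in 5 genes and in leaf in 2 (2 and 1 adjusted over the list alone; 16 and 4 with the block; adjusted p = 0.02505, 0.526 with an estimated correlation). Laccases were higher in stem in 1 of 14 (0 adjusted over the list alone; 1 in stem and 1 in leaf with the block; adjusted p = 0.0479, 0.526 with an estimated correlation). In the ribosome list the median (-0.51) and camera (adjusted p = 0.0435, 0.790 with an estimated correlation) pointed to stem. Nevertheless 27 of 407 genes were higher in leaf and 2 in stem (22 and 1 adjusted over the list alone; 41 and 7 with the block). These calls were lost in fits with a single library left out. Oligopeptide transport was lost without leaf s1 (0.0998), cell wall without leaf s1 (0.192) or stem s2 (0.324), and auxin without leaf s2 (0.127). Laccases were lost without leaf s1 (0.0953), without stem s1 (0.150) and with the block (0.0687). Flavonoid genes were lost without leaf s1 (0.0823), leaf s2 (0.139), root s1 (0.0652), root s2 (0.0611) or stem s1 (0.261). Ribosome genes were lost without leaf s1 (0.180), leaf s2 (0.148), root s1 (0.0652) or root s2 (0.0704) and with the block (0.0708). Their direction turned without stem s2 (0.429).

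Between leaf and stem, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1746 genes, 1137 higher in leaf and 609 higher in stem. With the replicate block it called 3085. Adjusted p of the genes named as higher in leaf or in stem lay between 0.0159 for LOC111878432 and 0.0491 for LOC111904178 by this test. The count was 161 without root s1, 1060 without stem s1, 2082 without stem s2 and 0 without leaf s1, leaf s2 or root s2. There 3865, 4431 and 4570 genes had an unadjusted p under 0.05. It was 234 in a fit of only the 2 tissues. Phenylpropanoid genes (7 of 198 higher in leaf, 14 in stem; 15 and 30 with the block) and peroxidase genes (4 and 8 of 102; 9 and 14 with the block) did not pass camera, at adjusted p = 0.0736 and 0.194.

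Root exceeded stem in phenylpropanoid and peroxidase genes. Cinnamate 4-hydroxylase LOC111876528 stood at 2647 ± 482 CPM in root and 157 ± 35.5 CPM in stem (SD, n = 2), a log2 fold change of 4.16 (SE 0.47). The chitinase LOC111884195 (chromosome 3, 26752074 to 26753333, plus strand) stood at 2073 ± 442 CPM in root and 42.3 ± 20.98 CPM in stem (log2 fold change 5.71, SE 0.80). Phenylpropanoid genes were higher in root in 20 of 198 and in stem in 3 (58 and 18 adjusted over the list alone, 53 and 12 with the replicate block, median 0.94). Peroxidase genes were higher in root in 10 of 102 (35 higher and 6 lower adjusted over the list alone, 29 and 5 with the block, median 1.10). Oligopeptide and nitrate transport genes were higher in root in 3 of 25 (6 adjusted over the list alone, 8 and 1 lower with the block, median 0.51). Nitrogen metabolism genes were higher in 2 of 41 (7 and 3 lower adjusted over the list alone, 6 and 2 with the block, median 0.91). Both are ammonium transporters, LOC111886494 (119 ± 38.2 against 9.64 ± 5.22 CPM) and LOC111886484 (102 ± 63.3 against 4.96 ± 0.737 CPM). By camera, adjusted p was 1.568e-07 for phenylpropanoid, 6.611e-09 for peroxidase, 0.0487 for transport and 0.0464 for nitrogen genes. They had adjusted p = 0.633, 0.633, 0.633 and 0.661 with an estimated correlation. The transport call was lost without leaf s1 (0.0917), leaf s2 (0.106), root s2 (0.0970), stem s1 (0.175) or stem s2 (0.08245). The nitrogen call was lost without leaf s1 (0.121), leaf s2 (0.140), root s1 (0.2725) or stem s2 (0.518).

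Stem exceeded root in the photosynthesis groups, in which stem s2 held the higher share (1.10%, against 0.283% in stem s1). Antenna genes were higher in stem in 2 of 27 (23 adjusted over the list alone, 13 with the replicate block, median -5.83, or -5.67 with genes at 0 at their bound). LOC111891773 had a log2 fold change of -6.58 (SE 0.98). Photosynthesis genes were higher in stem in 3 of 61 (32 adjusted over the list alone, 22 with the block, median -4.09, or -3.23 with genes at 0 at their bound). Chlorophyll genes were higher in 3 of 47, with 1 higher in root (19 and 1 adjusted over the list alone, 14 and 1 with the block, median -1.61). Circadian genes were higher in stem in 2 of 61 and in root in 1 (9 and 1 adjusted over the list alone, 10 and 1 with the block, median -1.14, or -1.06 with genes at 0 at their bound). Phytochrome B, LOC111918140, stood at 115 ± 83.04 CPM in stem and 4.002 ± 1.75 CPM in root. Circadian genes took 0.131% of counts in stem s1 (Wilson interval 0.126 to 0.136%) and 0.647% in stem s2 (0.637 to 0.657%). Xyloglucan genes were higher in stem in 1 of 28 (1 adjusted over the list alone, 7 with the block, median -1.51). The transferase LOC111909618 stood at 36.3 ± 12.6 CPM in stem and 1.247 ± 0.459 CPM in root. Adjusted p by camera was 5.399e-10 for antenna and for photosynthesis, 1.874e-05 for chlorophyll, 0.00366 for circadian and 0.00734 for xyloglucan genes. The same lists had adjusted p = 0.633 with an estimated correlation for each of them. The circadian call was lost without stem s2 (0.0695), and the xyloglucan call without root s1 (0.134) or stem s2 (0.375).

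Microtubule genes (66 tested, median -0.74, 17 at an unadjusted p under 0.05) and DNA replication genes (51 tested, median -0.62, 7 at an unadjusted p under 0.05) passed camera toward stem, at adjusted p = 0.00134 and 0.0168 (0.633 with an estimated correlation for each). EdgeR called 0 single members of either in the fit without the block. With the replicate block it called 1 microtubule gene higher in root and 3 in stem, and 1 replication gene higher in stem. Against the camera direction, microtubule genes took a higher share of counts in root s2 (0.263%, Wilson interval 0.256 to 0.270%) than in either stem library. Stem s1 held 0.138% (0.133 to 0.143%) and stem s2 0.175% (0.170 to 0.181%). Root s1 (0.175%, 0.169 to 0.181%) lay above stem s1 and level with stem s2. DESeq2 called 1 microtubule gene higher in root and 2 in stem, and 0 replication genes. Ribosome genes passed toward root (median 0.24, 2 of 407 genes higher in root, 5 and 2 lower with the block, adjusted p = 0.00734, 0.851 with an estimated correlation). The microtubule call was lost without stem s2 (0.08245), the replication call without root s2 (0.1185) or stem s2 (0.129) and the ribosome call without root s1 (0.199). The ribosome direction turned without stem s1 (0.551).

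Between root and stem, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 498 genes, 300 higher in root and 198 higher in stem. With the replicate block it called 1986. Adjusted p of the named genes by this test lay between 0.0367 for LOC111876528 and 0.0458 for LOC111918140. The share higher in root was 60.2%, against 49.9% of the 2097 calls of DESeq2 and 52.1% with the block. The count was 1415 without stem s1 (48.55% higher in root), 211 without stem s2 (36.49% higher in root), 704 in a fit of only the 2 tissues and 0 without either leaf or either root library. In the fits with 0 calls between 2607 and 4560 genes had an unadjusted p under 0.05. Nucleosome genes did not pass camera (adjusted p = 0.0908), with 0 of 131 called by edgeR (6 higher in root and 1 in stem with the block), 16 at an unadjusted p under 0.05 and 9 higher in root and 1 in stem by DESeq2.

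In 17 tested lists no comparison passed camera, adjusted p running from 0.0816 (cellulose biosynthesis, root vs stem) to 0.997 (plant-pathogen interaction, leaf vs root). Between leaf and root, transcription factor genes were higher in leaf in 49 of 579 and in root in 77 (51 and 78 adjusted over the list alone). Hormone signalling genes were higher in 41 and 50 of 426 (41 and 51), defense response genes in 19 and 33 of 235 (21 and 37). Plant-pathogen interaction genes were higher in leaf in 36 and in root in 35 of 312 (36 and 36) and starch and sucrose genes in 33 and 21 of 192 (38 and 24). Glutathione genes were higher in leaf in 16 and in root in 11 of 71 (18 and 15 adjusted over the list alone), aquaporins in 8 and 14 of 48 (10 and 15). Lipid transport genes were higher in 6 and 12 of 49 (8 and 13), cutin, suberin and wax genes in 8 and 11 of 51 (19 and 14) and NBS-LRR genes in 12 and 8 of 179 (9 and 2). Terpenoid backbone genes were higher in leaf in 14 of 53 (15 adjusted over the list alone) and terpene synthases in 3 of 12 (3). Sesquiterpenoid and triterpenoid genes were higher in leaf in 6 and in root in 3 of 29 (6 and 4), zeatin genes in 5 and 3 of 29 (5 and 4). Germin-like genes were higher in 3 and 1 of 19 (4 and 2), cellulose genes in 2 and 2 of 33 (2 and 2) and spliceosome genes in 5 and 6 of 169 (2 and 2). DESeq2 turned the balance of calls for sesquiterpenoid and triterpenoid genes (6 and 7) and for cutin, suberin and wax genes (15 and 11). The replicate block turned it for sesquiterpenoid and triterpenoid (7 and 8), zeatin (5 and 6) and cutin, suberin and wax genes (17 and 15). It also moved defense response (29 and 44), NBS-LRR (20 and 12), glutathione (19 and 17), cellulose (6 and 4), germin-like (3 and 2) and terpenoid backbone genes (16 and 2). Brassinosteroid biosynthesis had 1 tested gene and could not be tested as a list.

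Tissue-enriched genes numbered 970 in leaf, 254 in root and 40 in stem, and 1550, 804 and 219 with the replicate block. Leaf-enriched genes of highest level were LOC111884730, LOC111910617 and LOC111891773, given above, followed by photosystem I subunit PsaN, LOC111904178 (chromosome 1, 11945189 to 11946276), at 3946 ± 858 CPM in leaf, 6.14 ± 0.208 in root and 259 ± 265 in stem (SD, n = 2). ACC oxidase LOC111890969 (chromosome 7, 17887766 to 17890436) stood at 3132 ± 2601 CPM in leaf and 244 ± 78.5 CPM in stem. Phosphoenolpyruvate carboxylase LOC111913734 (chromosome 7, 173030963 to 173037399) stood at 2671 ± 900 CPM in leaf, 399 ± 234 in root and 317 ± 5.83 in stem. The palmitoyl-glycerolipid desaturase LOC111897379 (chromosome 5, 6997659 to 6999065) stood at 157 ± 8.39 CPM in leaf with 0 counts elsewhere, at least 212.8-fold above root and 243.2-fold above stem. Among 920 GO terms, 47 were over-represented in the leaf-enriched genes by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment. They hold 136 of 468 chloroplast genes against 24.2 expected (adjusted p = 1.012e-62), 70 of 169 thylakoid membrane genes against 8.75 (9.122e-43) and 8 of 13 photorespiration genes against 0.673 (4.277e-06).

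Root-enriched genes of highest level were cinnamate 4-hydroxylase LOC111876528 and chitinase LOC111884195, followed by LOC111906094 (chromosome 6, 17007545 to 17009371), annotated with GTPase activity, at 1254 ± 139 CPM in root, 69.5 ± 4.31 in leaf and 141 ± 8.68 in stem. Sucrose synthase LOC111899116 (chromosome 5, 267636871 to 267641445) stood at 769 ± 235 CPM in root against 24.7 ± 12.1 in leaf and 79.3 ± 12.7 in stem. The wall-loosening expansin LOC111895937 (chromosome 6, 89714017 to 89716141) stood at 701 ± 32.4, 15.8 ± 2.40 and 46.2 ± 16.2 CPM. The high-affinity sulfate transporter LOC111908227 was at least 84.77-fold higher in root than in leaf. The phosphate transporter LOC111891098 stood at 200 ± 71.4 CPM in root with a root to leaf ratio of 884.7 (counting interval 158.3 to 34990). In the root-enriched genes 9 GO terms passed, and 41 with the replicate block. They included heme binding (17 of 317 genes against 4.06 expected), peroxidase activity (10 of 102 against 1.30) and response to oxidative stress (10 of 105), each at adjusted p = 2.189e-04 by the same Fisher's test.

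Stem-enriched genes of highest level were LOC111891021 (chromosome 7, 43105639 to 43106770), annotated with a receptor-associated kinase KO and carbohydrate binding, at 2601 ± 1298 CPM in stem, 103 ± 68.6 in leaf and 2.37 ± 1.87 in root. A tropinone reductase gene, LOC111912423, stood at 579 ± 445 CPM in stem. The gene of an HtpG-type chaperone, LOC111888460 (chromosome 2, 211514138 to 211517340) stood at 320 ± 23.4 CPM in stem, 32.6 ± 13.9 in leaf and 41.4 ± 5.13 in root. The small heat shock protein LOC111907242 (chromosome 5, 310591331 to 310592361) stood at 201 ± 29.4, 44.0 ± 2.24 and 36.8 ± 0.550 CPM. A gene with the KO of SPEECHLESS, a transcription factor that starts the stomatal lineage, LOC111918110 (chromosome 6, 131874290 to 131875844), stood at 56.3 ± 27.2 CPM in stem and 1.61 ± 0.986 in leaf, with a stem to root ratio of 234.4 (counting interval 41.72 to 9294). The xyloglucan O-acetyltransferase LOC111916264 stood at 150 ± 37.4 CPM in stem against 7.13 ± 5.57 in leaf and 8.31 ± 0.637 in root. No GO term passed the one-sided Fisher's exact test in the stem-enriched genes (0 of 920, 17 at an unadjusted p under 0.05, and 0 with genes called under the block or with all tested genes as background).

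The number of enriched calls depended on which library was left out. All comparisons share a common estimate of the spread. A loss of calls therefore does not show that they rest on the values of the library left out. Without stem s1 there were 611 leaf-, 576 root- and 61 stem-enriched genes, without stem s2 1155, 69 and 55. With any leaf or root library left out edgeR's quasi-likelihood test called 0 in each tissue. DESeq2 with all libraries called 1349, 771 and 173.

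**Figure D3:**
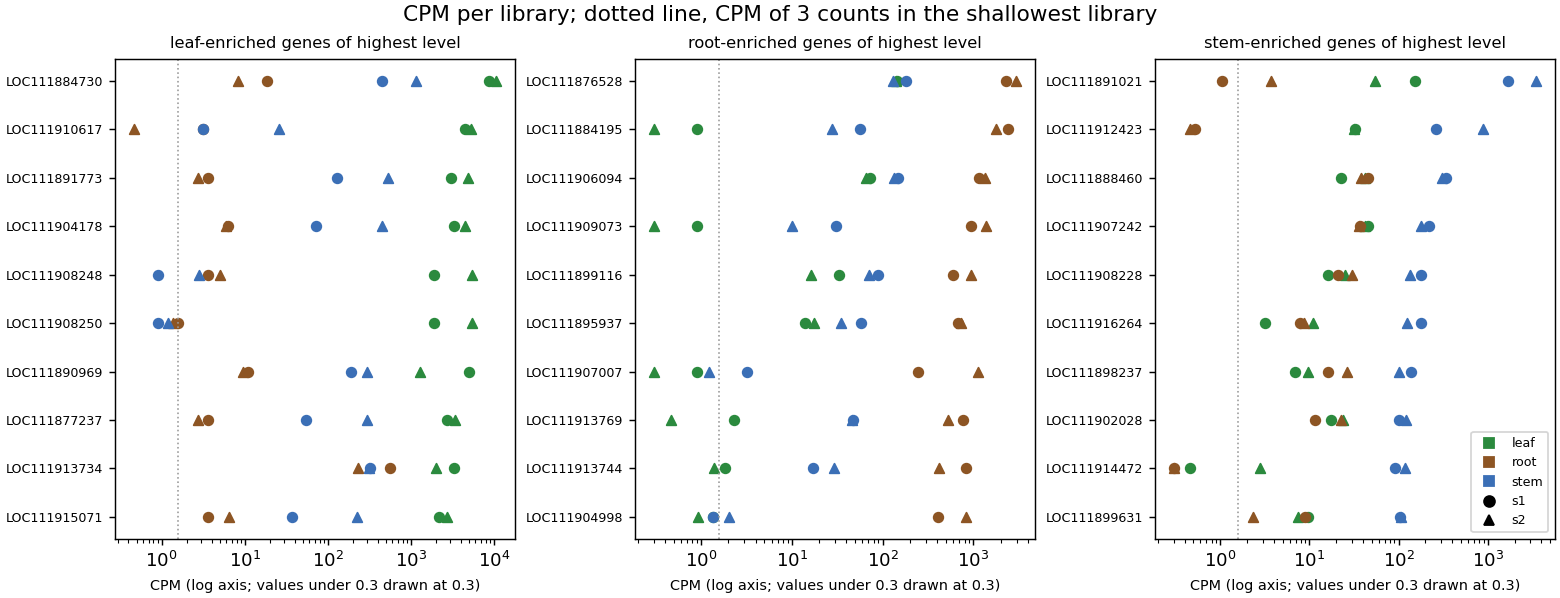
CPM in each of the 6 libraries (log axis, circles s1, triangles s2) of the tissue-enriched genes of highest level; values under 0.3 are drawn at 0.3, and the dotted line is the CPM of 3 counts in the shallowest library, 1.57. Leaf-enriched genes reach 9747 CPM (LOC111884730), root-enriched genes 2647 CPM (LOC111876528) and stem-enriched genes 2601 CPM (LOC111891021) as means of 2 libraries.

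The isoform table held 69973 isoforms of 22033 genes, of which 16163 (73.4%) had 2 or more isoforms and 4508 had 5 or more. Full splice matches made up 54.9% of the isoforms, incomplete matches 20.1%, and the NIC and NNC categories 13.1 and 11.9%. By UMIs the full splice matches weighed more, with 83.4 ± 0.0135% in leaf, 85.5 ± 0.429% in root and 84.4 ± 0.605% in stem (SD, n = 2). Both libraries of a single tissue, and no other library, held 972 isoforms in leaf, 852 in root and 458 in stem. The merged gene models held 117602 transcripts, 49106 of them (41.8%) added by the merge, with a median of 6 exons against 4 in the reference transcripts. Single-exon transcripts made up 0.0% of the added and 17.0% of the reference transcripts, so these medians compare unlike sets.

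Between leaf and root edgeR's quasi-likelihood test called 4977 of 24280 isoforms (3041 higher in leaf, 1936 in root), between leaf and stem 2220 (1621 and 599; 3906 with the replicate block), and between root and stem 491 (305 and 186; 2544 with the block). Leaf-enriched isoforms numbered 1410 from 867 genes, root-enriched isoforms 269 from 203 genes and stem-enriched isoforms 39 from 36 genes (2267, 1009 and 263 isoforms with the block). The gene itself was enriched in the same tissue for 84.0% of the leaf-, 81.4% of the root- and 71.8% of the stem-enriched isoforms. With single libraries left out the counts ranged from 0 to 6878 between leaf and root, 0 to 2980 between leaf and stem and 0 to 2065 between root and stem.

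Changes in the share of an isoform within its gene were called in few genes. In LOC111906094, the root-enriched gene above, the incomplete splice match PB.59628.25 made up 6.78 ± 0.84% of the UMIs of the gene's tested isoforms in leaf and 45.2 ± 6.18% in root (SD, n = 2; Simes adjusted p = 0.0137). In LOC111910182, a 3-hydroxybutyryl-CoA dehydrogenase gene, the full splice match PB.53963.6 made up 30.2 ± 6.43% of such UMIs in root and 1.24 ± 1.34% in stem (adjusted p = 0.0157). The other leaf vs root call, LOC111894257, had as few as 43 UMIs in a library and was chosen after its values were seen. Its incomplete splice match PB.20457.1 rose from a mean of 4.94% of such UMIs in leaf to 72.0% in root (Simes adjusted p = 0.00346). The replicate block also called this gene in leaf vs stem (Simes adjusted p = 0.0292). Both leaf vs root calls thus concern incomplete splice matches. Whether these are truncated copies of longer transcripts was not tested. By diffSpliceDGE of edgeR 2 of 6348 genes were called between leaf and root, 0 between leaf and stem and 1 between root and stem, with 40, 31 and 35 at an unadjusted p under 0.05. The diffSplice test of limma called 4, 2 and 2. With each library left out in turn the calls ranged from 0 to 2, stayed at 0, and ranged from 0 to 1. A test with the gene UMI total as offset, added after the data were seen, called 4, 0 and 3 of 4949 genes, among them cysteine synthase LOC111890748, whose PB.55369.8 made up 2.77 ± 0.85% of all UMIs of its gene in leaf and 43.1 ± 0.24% in root (adjusted p = 0.00143).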

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

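Numbers of calls depended on the libraries and settings, while directions mostly held. Of 248 called results for named genes, DESeq2 kept 245, RLE scaling 246, no low-count filter 242 and the replicate block 247. Of 142 not called, these called 44, 3, 22 and 32. Leaving out 1 library at a time kept 593 calls and ended 895. A fit of only the 2 tissues compared kept 182 and ended 65. Beside the values given here and with the results, the block changed no other camera call of a list. Groups of 2 libraries left the spread poorly known, and the lone library of a group with 1 left out was assumed to vary like the others. Genes near the floor of 3 counts (1.21 to 1.57 CPM) could not be told from absent. For each count below, the cause was not tested.

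DESeq2 gave 2862 genes for leaf vs stem, 2097 for root vs stem, 771 root- and 173 stem-enriched genes, 1780 isoforms for root vs stem, and 669 root- and 105 stem-enriched isoforms. At adjusted p under 0.01, 805 genes and 877 isoforms were left for leaf vs root, 0 genes and 0 isoforms for leaf vs stem, 0 and 0 for root vs stem, and 0 enriched genes or isoforms of leaf (0 and 0), root (0 and 0) and stem (0 and 0). With no low-count filter, root vs stem had 1525 genes and 2275 isoforms, leaf vs stem 3605 isoforms, root-enriched 655 genes and 1064 isoforms, and stem-enriched 133 genes and 177 isoforms. The replicate block gave 3085 genes and 3906 isoforms for leaf vs stem and 1986 genes and 2544 isoforms for root vs stem. With it, enriched genes were 1550 in leaf, 804 in root and 219 in stem, enriched isoforms 2267, 1009 and 263, root GO terms 41, and isoform usage in leaf vs stem 1. Only the 2 tissues compared gave 234 genes and 1056 isoforms for leaf vs stem and 1192 isoforms for root vs stem.

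Isoform usage by limma voom and diffSplice called 4, 2 and 2 genes (leaf vs root, leaf vs stem, root vs stem). No minimum change of share called 1 in leaf vs stem. The gene total as offset called 4 in leaf vs root and 3 in root vs stem, and 12, 2 and 9 with the replicate block. Gene lists with an estimated correlation passed 0, 0 and 0 times.

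With 1 library left out, genes ranged from 0 to 4983 (leaf vs root), 0 to 2082 (leaf vs stem) and 0 to 1415 (root vs stem), enriched genes from 0 to 1155, 0 to 576 and 0 to 61 (leaf, root, stem). Isoforms ranged from 0 to 6878, 0 to 2980 and 0 to 2065, enriched isoforms from 0 to 1790, 0 to 849 and 0 to 183, and usage from 0 to 2, 0 to 0 and 0 to 1. Lists passing ranged from 12 to 14, 13 to 20 and 8 to 11. The list ribosome leaf vs stem ranged from adjusted p = 1.017e-06 to 0.4286, reversed without stem s2 (0.4286), and the list ribosome root vs stem from 3.976e-10 to 0.5511, reversed without stem s1 (0.5511).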

Other observations

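Some genes followed the s number of the library across all tissues; the 2 named here were chosen after their values were seen. The chitinase gene LOC111897167 stood at 285 CPM in leaf s1, 10.5 in root s1 and 1055 in stem s1, and at 0, 0 and 1.62 CPM in the s2 libraries. The expansin gene LOC111879516 stood at 157, 269 and 117 CPM in the s1 libraries of leaf, root and stem and at 0, 0.922 and 2.02 CPM in s2. In a fit with tissue and s number, added after the data were seen, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 19 of 19601 genes, 8 higher in s2 and 11 higher in s1. Between s1 and s2, camera with Benjamini-Hochberg adjustment passed 15 of 37 lists at the preset correlation and 0 with a correlation estimated from the data. Nucleosome (adjusted p = 2.745e-09, 0.8401 with the estimated correlation) and antenna proteins (3.078e-06, 0.8463) passed toward s2, and defense response (0.03475, 0.8463) toward s1. EdgeR called 0 single members of the nucleosome or antenna list. The nucleosome share of counts fell from s1 to s2 in leaf (0.913 to 0.603%) and stem (1.58 to 1.48%) and rose in root (1.48 to 2.12%). The antenna share rose in leaf (3.71 to 4.22%) and stem (0.0703 to 0.503%) and fell in root (0.0076 to 0.0058%). What the s number stands for is not given in the sources used here.

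The s1 minus s2 difference was shared between tissues (mean correlation 0.3391), and its length, low-count, time-of-day and split tests were set before their values were seen, though the summed share of circadian genes had been seen. A trend with the longest annotated transcript of each gene was excluded as its source, the correlation being 0.3399 after that trend was removed. A bias by the length of the isoforms expressed was not tested. Low counts were excluded too, with 0.3785 in the top 25% of genes by counts. Morning minus evening clock genes, s2 minus s1, differed by -0.1748 in leaf (SE over genes 0.3488), -0.3319 in root (0.4047) and 0.2511 in stem (0.3787). A shift of 1 in log2 of either sign lay over 2 SE away in 2 tissues. This margin per sign was set after these values were seen. The test held 8 morning and 5 evening genes, and its SE covers the spread over genes only. It leaves a smaller shift open, so different times of day were not excluded. The circadian list passed camera toward s2 (adjusted p = 0.01467, 0.8401 with an estimated correlation). Its share of counts in s1 and s2 was 0.259 and 0.321% in leaf, 0.0998 and 0.1755% in root, and 0.131 and 0.647% in stem. The real split was the only 1 of 10 splits with as many called genes (19, the highest other 0), too few splits to reach a share of 0.05. Splits that keep both libraries of a tissue together rest on 1 tissue alone in this fit, so their 0 calls say little. The split test therefore decides nothing.

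The stem libraries differed more than those of leaf or root, and all carry-over tests were chosen only after this was seen. Of 131 leaf-abundant genes, 26.72% lay in stem s2 below 0.5 of the antenna share (12.67% of leaf level). This argues against leaf tissue with the profile of the leaf libraries as the whole source of the photosynthesis RNA there. The median share of those genes was 13.02%, near the antenna share. Partial carry-over, or leaf tissue of another profile, is left open. For root tissue in stem s1, the test of 69 root-abundant genes against their own median share (26.09% lay below 0.5 of it) decides nothing. Root shares up to 7.7% were tried, above which over 10% of those genes lay too low. With root RNA taken out of stem s1 or mixed into stem s2, the stem correlation reached at most 0.7813, against 0.7637. It was highest at 7.7%, the largest share tried. Most of the gap to the leaf pair (correlation 0.872) thus stayed. This argues against root tissue with the mean profile of the root libraries, at those shares, as its main source. Larger shares, or root tissue of another profile, are left open. For depth, the correlation was 0.7629 after the deeper stem library was thinned from 2475316 to 2187368 counts. The totals were so close that thinning could hardly have moved it, so this test decides nothing. No biological explanation was tested.

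Tests of a genetic difference between the s1 and s2 libraries, by all-or-none genes and by position, were chosen only after such genes were seen. There were 7 genes over 20 CPM in all 3 libraries of one s number and at most 1 CPM in the others, against 0 in each of 3 mixed splits. This counts again the genes that prompted the test and decides nothing. By position, 0 pairs lay within 500 kb, and 7 genes were too few to tell.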
